A study of Homo sapiens with 9 samples.

How the data were processed

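RNA was measured in 9 libraries from tumorspheres of HDMB03, an established cell line of Group 3 medulloblastoma, a childhood tumour of the cerebellum. Per the labels, the spheres grew in serum-free neural stem cell medium and were transduced at a multiplicity of infection of 0.3 with lentivirus carrying the open reading frame of PAX3, of PAX6 or of red fluorescent protein (RFP) as the control. The labels place 3 libraries in each of the 3 groups, and these are called control, PAX3-GOF and PAX6-GOF (gain of function), with the replicate numbers of the sample titles. Libraries were made with an unstranded TruSeq RNA v2 kit, per the labels' protocols, so reads of a gene and of an antisense or overlapping neighbour cannot be told apart and the values of such genes are uncertain. Nothing in the sources used here says whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

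The authors quantified transcripts with Salmon 0.9.1, used DESeq2 and worked on GRCh38, per the submitters' processing notes; the annotation release and the read filters are not given in the sources used here. Each library's deposited table holds estimated counts of reads per transcript, not normalized, per the file headers. The deposited tables also hold TPM (a share of transcripts scaled by length) per the file headers, and other columns with the effective transcript length in bases per the file headers. The TPM values served only to weight the effective lengths of the transcripts of a gene in the length offset described below. Another pair of deposited tables holds the authors' own comparisons of PAX3-GOF and of PAX6-GOF with control, with DESeq2 column names per the file headers. Their mean signal over libraries is the deposited mean of normalized counts, their log2 fold changes and standard errors are the authors' estimates, and their p-values and adjusted p-values were deposited as the authors computed them. These tables were used only to set the authors' calls beside the ones made here.

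Transcript identifiers were matched to the annotation of GENCODE release 29 on GRCh38. Of 199704 transcripts 199368 matched (99.83%), and their estimated counts were summed over 57721 genes and rounded to whole numbers. The share of estimated reads on unmatched transcripts was 0.0552 to 0.0914% per library and was left out. Library totals ranged from 42903801 to 85085728 estimated reads. Intervals and floors given for counts cover counting error only, because the reads carry no molecular identifiers. A gene with 0 counts in a group was set at 3 counts over the group to give a lower bound on its fold, and a gene with 1 to 3 counts was given as a ratio with an exact 95% counting interval.

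Differences between groups were tested with edgeR 4.0.16 in R 4.3.3. The fit took all 9 libraries with 1 coefficient per group (6 residual degrees of freedom), trimmed-mean scaling (TMM), the filterByExpr filter (21873 genes tested) and the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05, and changes are log2 fold changes with standard errors (SE). Levels are CPM (counts scaled to a common library total of 1e6) on the TMM library sizes, as mean ± standard deviation (SD). Before the data were examined, 32 gene lists were fixed for pathways and cell types relevant to medulloblastoma, to PAX3 and to PAX6, with RNA quality, handling and other cell types among them. Each list was tested against the other genes with camera in limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 32 lists of a comparison. No list passed the threshold when the correlation was estimated from these libraries, so every list result rests on the preset value.

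The rule for the genes named was also fixed before the data were examined. It takes PAX3, PAX6 and OTX2, and for each comparison with control the 10 higher and 10 lower protein-coding genes with the largest change. These had to be past the threshold, with a mean of at least 1 CPM and no overlap between the libraries of both groups. For PAX3-GOF against PAX6-GOF it takes 5 and 5, and for each gene list described up to 4 members with the smallest adjusted p. Some genes outside this rule are named too, and some list members it takes are not reported here.

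The alternatives chosen before the data were examined were DESeq2 size factors and upper-quartile scaling, no filter on low counts and a strict filter (over 1 CPM in 3 libraries), DESeq2 1.42.0 and limma-voom. The others were a fit of the compared groups alone, a length offset per gene and library, the replicate number as a block, estimated correlation and fry for the gene lists, and leaving out each of the 9 libraries in turn. After the data were examined, a positional adjustment was added, which removes the running median of 51 neighbouring expressed genes along each chromosome, as was a test without the genes of chromosomes 8, 10, 16 and 18. Comparisons against the same control libraries share their chance values, so unchanged groups were simulated in 50 runs per setting. The settings were 1 spread for all groups and then the own spread of each group. Each run drew all 9 libraries, controls included, gene by gene around the control means. Differences between the real control libraries that run over many genes are therefore left out.

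The tests were run on simulated counts drawn from the real means and library sizes over 21873 genes. Changes were put into 200 genes per gain-of-function group, all with a mean of at least 1 CPM. For PAX3-GOF against control edgeR recovered 3% of the 1.5-fold, 35.8% of the 2-fold and 90.9% of the 4-fold changes. For PAX6-GOF against control it recovered 4.5%, 34.3% and 87.9%, and for PAX3-GOF against PAX6-GOF 11.9%, 47% and 93.2%. It called 4, 4 and 13 of 20360 unchanged genes in these comparisons. Changes of 2-fold or less are therefore mostly missed at this size. These counts were drawn gene by gene with 1 spread per gene for all groups. The wider spread of the real controls and deviations of libraries over many genes are left out, so the rates in the real comparisons may differ. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.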

Results

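The data are gene expression levels of HDMB03 tumorspheres that carried a PAX3, a PAX6 or an RFP control lentivirus, with 3 libraries per group. PAX3 and PAX6 are paired-box transcription factors of the developing nervous system, and OTX2 is a homeobox transcription factor that is highly expressed in Group 3 medulloblastoma. The design asks what each PAX gene changes in these cells, in a study of how OTX2 and PAX3 act on the fate of the tumour cells. The control libraries 1, 3 and 4 held 85085728, 47743879 and 52324686 estimated reads. The PAX3-GOF libraries 1, 4 and 5 held 44727979, 51732165 and 54932415, and the PAX6-GOF libraries 1, 2 and 3 held 42903801, 50032065 and 52918303. Mitochondrial transcripts took 4.53 to 7.49% of the reads and protein-coding genes 92.6 to 95.8%. Within groups, pairs of libraries differed by 43.6 to 273.52 times sampling noise (chi-square per degree of freedom over genes), so no library was a copy of another. The first principal component (37.5% of the variance) placed the PAX3-GOF libraries at one end and the PAX6-GOF libraries at the other. Control 3 (39.2) lay near PAX3-GOF 4 (45.7) on it, apart from controls 1 and 4 (-13.3 and -9).

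The transduced genes were high in the libraries labelled for them. PAX3 (ENSG00000135903, chromosome 2, 222199888 to 222298996, GRCh38) had 0 counts in the 3 control libraries and lay at 86.3, 74.9 and 79.7 CPM in the PAX3-GOF libraries, 80.3 ± 5.69 CPM (SD, n = 3). Against a floor of 3 counts over the control group, PAX3 was at least 4980-fold higher (edgeR adjusted p = 1.45e-06, higher in 3 of 3 libraries), and the PAX6-GOF group held 1 PAX3 count. PAX6 (ENSG00000007372, chromosome 11, 31784779 to 31818062) lay at 5.57, 21.5 and 7.14 CPM in the control libraries and at 83.3 ± 7.16 CPM (SD, n = 3) with the PAX6 virus. This was a rise of 2.87 ± 0.57 (log2, SE; edgeR adjusted p = 0.0199, higher in 3 of 3 libraries). The PAX6 call was lost without control 4 (adjusted p = 0.0695) and without PAX6-GOF 1, 2 or 3 (0.0571, 0.0673 and 0.0677). In PAX3-GOF spheres PAX6 lay at 5.81 ± 3.44 CPM, a difference from control of -0.96 that did not pass (edgeR adjusted p = 0.410). OTX2 (ENSG00000165588, chromosome 14, 56799905 to 56810479) lay at 1222 ± 46.4 CPM in control, 1486 ± 196 CPM in PAX3-GOF and 1696 ± 62.0 CPM in PAX6-GOF (SD, n = 3). Neither difference in OTX2 passed with edgeR, at 0.28 ± 0.14 (adjusted p = 0.318) and 0.47 ± 0.14 (adjusted p = 0.0893). With DESeq2 the PAX6-GOF difference in OTX2 was 0.50 and passed (adjusted p = 0.00671), and the authors' deposited table gives OTX2 a log2 fold change of 0.435 with adjusted p = 0.041.

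**Figure D1:**
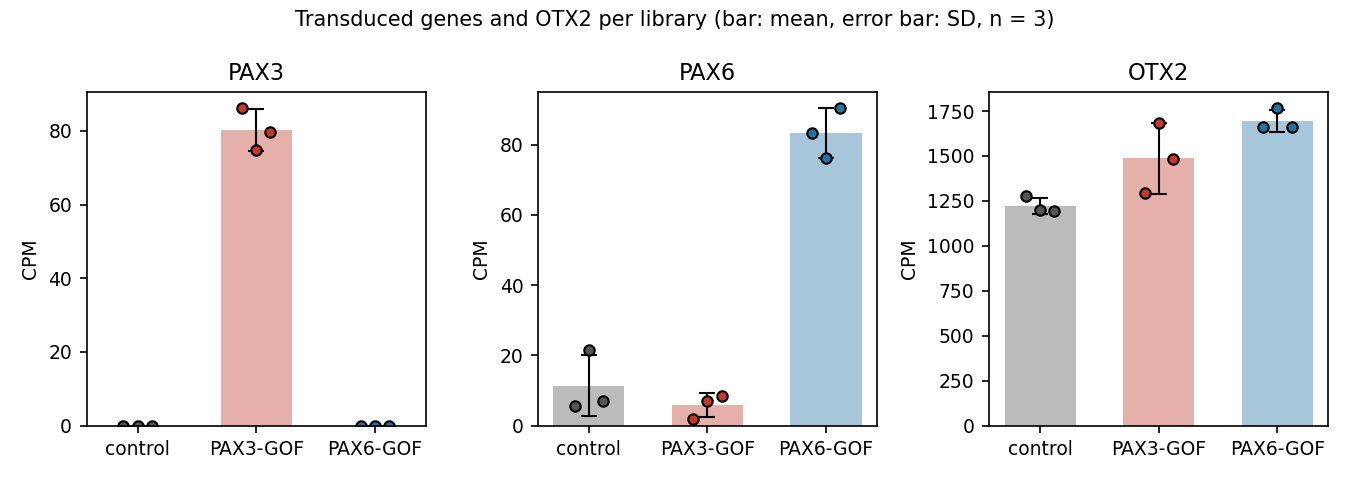
CPM of PAX3, PAX6 and OTX2 per library (points), with group means (bars) and SD (error bars) over 3 libraries. PAX3 lies at 0 in every control library and at 74.9 to 86.3 CPM in PAX3-GOF, and PAX6 at 83.3 CPM on average in PAX6-GOF against 11.4 CPM in control.

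PAX3-GOF spheres lost SOX2 and neurofilament transcripts and gained cyclin D2 and the homeobox gene ALX4. SOX2, a transcription factor of neural stem cells, lay at 53.6 ± 31.2 CPM in control and 1.28 ± 0.43 CPM in PAX3-GOF (SD, n = 3), a log2 change of -5.38 ± 0.51. ALX4, a homeobox transcription factor, went from 0.032 to 79.4 ± 69.0 CPM (11.17 ± 0.95), with 18.1, 65.8 and 154 CPM in the 3 PAX3-GOF libraries. CCND2, which encodes cyclin D2, rose from 44.5 ± 35.2 to 970 ± 90.5 CPM (4.45 ± 0.55), while CCND1, which encodes cyclin D1, changed by -4.17 ± 0.53 to 0.182 CPM. All lay beyond every control library, with edgeR adjusted p-values of 0.000212, 0.000107, 0.00107 and 0.00125.

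In all, 1202 of 21873 genes differed between PAX3-GOF and control by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 630 higher and 572 lower, of which 891 changed over 2-fold. After PAX3 and ALX4, the largest fitted rises among protein-coding genes with a mean of at least 1 CPM were in SYNDIG1, SPP1, C2CD4C, PID1, FSTL4, MPPED2, CCDC33 and ADGRG1. SYNDIG1, a regulator of excitatory synapses, had 856 counts against 1 in control, a ratio of 1050 (95% counting interval 189 to 41700). SPP1, which encodes osteopontin, rose from 0.028 to 15.0 CPM, C2CD4C by 8.68 ± 0.51 and PID1 by 8.65 ± 0.73. FSTL4 rose by 7.90 ± 0.65, MPPED2 by 7.33 ± 0.48 and CCDC33 by 7.19 ± 0.59. ADGRG1, an adhesion receptor of cortical development, was the most abundant of them at 221 ± 82.0 against 1.79 ± 0.49 CPM (6.95 ± 0.38; edgeR adjusted p = 9.42e-06). Of the lower genes under the same limits, lipoprotein lipase (LPL) fell furthest, with a change of -6.09 ± 0.44 from 32.2 to 0.468 CPM. SOX2 was followed by the neuronal splicing factor NOVA1 (-5.23 ± 0.36), the synaptic adhesion gene TENM4 (-4.70 ± 0.30) and the light neurofilament gene NEFL (-4.57 ± 0.37). TBX1 (-4.36 ± 0.45), TMEM101 (-4.32 ± 0.34), the potassium channel subunit KCNV2 (-4.26 ± 0.40) and CILP2 (-4.17 ± 0.43) completed the list with CCND1. The largest adjusted p among these genes was 0.00125. In each the 3 PAX3-GOF libraries lay beyond all 3 controls, which the rule for named genes required and which is therefore no further evidence. Such separation of 3 from 3 libraries occurs in 10% of unchanged genes by chance, and 20.5% of all tested genes showed it here (23.7% for PAX6-GOF against control and 40.4% for PAX3-GOF against PAX6-GOF).

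Among the fixed gene lists, 6 of 32 shifted lower in PAX3-GOF by camera and none higher. In the synapse and ion channel list 2 of 35 measured genes rose and 5 fell (camera adjusted p = 0.00718; adjusted p = 0.383 with an estimated correlation), and adjusted over the list alone 4 rose and 9 fell. The glutamate receptor gene GRIA1 fell by 2.34 on the log2 scale, while GAD1, which makes GABA, rose by 4.02. The scaffold gene SHANK2 also rose, by less (2.82-fold). With the length offset the call of SHANK2 was lost (edgeR adjusted p = 0.102). In the list of ATF4 and amino acid genes 4 of 25 fell and 1 rose (camera adjusted p = 0.0041; adjusted p = 0.563 with an estimated correlation), and 4 fell and 2 rose adjusted over the list alone. SESN2, an inhibitor of mTORC1, changed by -1.47 ± 0.20, CEBPB by -1.15 ± 0.20 and DDIT4, another mTORC1 inhibitor, by -1.99 ± 0.39, while ATF5 rose by 1.11 ± 0.27 (edgeR adjusted p = 0.0381 for ATF5, the largest). The glycolysis and hypoxia list (camera adjusted p = 0.00136; adjusted p = 0.563 with an estimated correlation) had 1 called gene of 29, the glucose transporter gene SLC2A1 (-0.89 ± 0.16, 91.4 against 49.2 CPM). Adjusted over the list alone, 7 of its genes were lower. In the list of p53 targets 4 of 27 fell (7 lower and 1 higher adjusted over the list alone), namely CDKN2D (-1.56 ± 0.27), BAX, SESN1 and GDF15 (camera adjusted p = 0.00136; adjusted p = 0.633 with an estimated correlation). The inhibitor gene CDKN2A, outside this list and the rule for named genes, rose by 3.04 ± 0.46 (edgeR adjusted p = 0.00337, higher in 3 of 3 libraries). The unfolded protein response list had 1 of 24 genes lower over all genes and 1 adjusted over the list alone, CRELD2 (-0.91 ± 0.21; camera adjusted p = 0.00358, adjusted p = 0.563 with an estimated correlation). The cholesterol synthesis list shifted lower with 0 of 25 genes called in either count (median -0.40; camera adjusted p = 0.00145, adjusted p = 0.563 with an estimated correlation). HMGCS1, its most changed gene by p, stood at -0.97 ± 0.31 (edgeR adjusted p = 0.113; p under 0.05 in 3969 genes overall).

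Neuronal and photoreceptor genes fell individually without their lists passing. Of 29 neuronal differentiation genes 5 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.0702). NEFL, MAP1B (-1.04), the medium neurofilament gene NEFM (-4.01) and the growth-cone gene GAP43 (-2.13) led them. Of 36 photoreceptor genes 5 fell (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.061), led by the cone phosphodiesterase gene PDE6C (-3.04) and the thyroid receptor gene THRB (-2.51). In the progenitor list SOX2 and HMGA2 (-0.87) fell while SOX11 rose by 1.19, and of its 24 genes 1 rose and 3 fell (2 and 4 adjusted over the list alone) without the list passing camera. The myogenic list had 3 of 24 genes higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 0.154). Its higher genes were the PAX3 partner EYA1 (4.75 ± 0.45), the muscle progenitor receptor FGFR4 (1.34 ± 0.22) and EYA4, with 68 against 2 counts (ratio 41.9, counting interval 11.2 to 353). The muscle structural genes MYH3 (726 CPM) and ACTC1 (265 CPM) and the muscle regulator MYOG (196 CPM) were highest in the library PAX3-GOF 1, at 7.52 to 8.61, 1.32 to 2.02 and 15.6 to 17.4 CPM in PAX3-GOF 4 and 5. The controls held 11.2 to 44.2 CPM of MYH3 and 30.3 to 81.7 CPM of MYOG, above PAX3-GOF 4 and 5, and without PAX3-GOF 1 the comparison called 1106 genes.

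**Figure D2:**
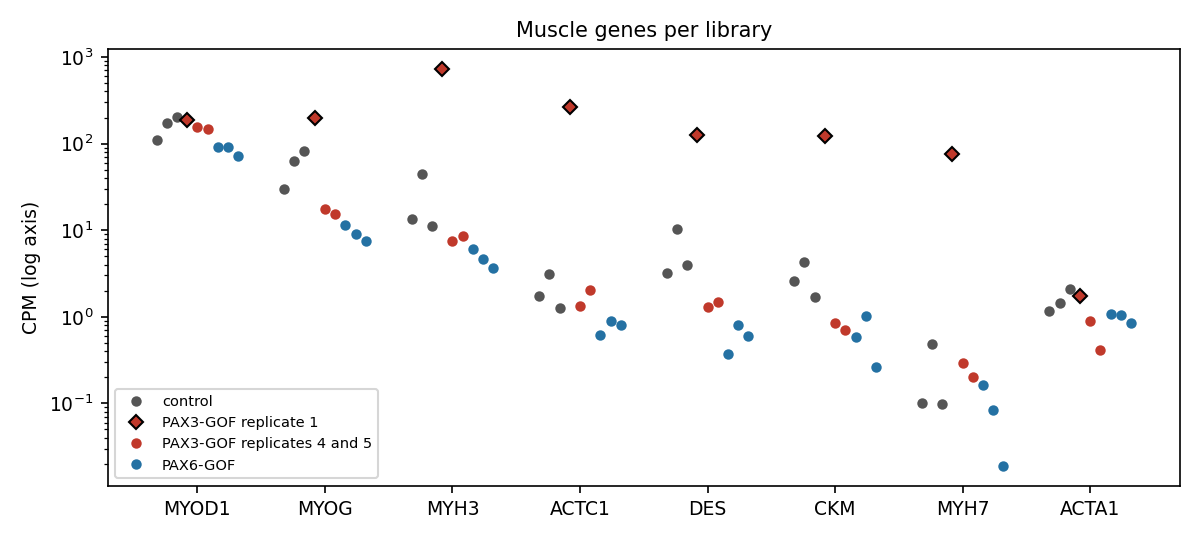
CPM (log axis) of 8 muscle genes per library, 1 point per library, with PAX3-GOF 1 as a diamond. MYH3 lies at 726 CPM in PAX3-GOF 1 and at 7.52 and 8.61 CPM in PAX3-GOF 4 and 5, while ACTA1 lies at 1.75 CPM in PAX3-GOF 1.

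The number of genes differing between PAX3-GOF and control was 672 without PAX3-GOF 5, 735 without PAX3-GOF 4 and 2193 without control 3, 612 when only these 6 libraries were fitted and 1954 with DESeq2. The ATF4 and unfolded protein response lists no longer passed camera without control 4 (adjusted p = 0.06 and 0.0569), nor did the p53 list without control 3 (0.132). Leaving out single libraries ended the calls of DDIT4 (without PAX3-GOF 4, 0.0598) and of ATF5, BAX, SESN1, GDF15 and CRELD2 (edgeR adjusted p up to 0.0946, 0.154, 0.162, 0.166 and 0.115 without 1 library).

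PAX6-GOF spheres gained transcripts of FEZF2, MAP2, LAMA1 and MAF and lost those of TWIST1, DCN and LUM. FEZF2, a transcription factor of forebrain neurons, rose from 0.271 to 39.4 ± 12.2 CPM (7.03 ± 0.67) and the microtubule gene MAP2 rose by 2.30 ± 0.25. LAMA1, a laminin chain of basement membranes, went from 3.79 ± 1.16 to 67.5 ± 11.3 CPM (4.15 ± 0.27), and MAF, a transcription factor of lens development, rose by 5.35 ± 0.69. TWIST1, a regulator of mesenchyme, fell from 26.5 ± 12.1 to 0.527 ± 0.21 CPM (-5.65 ± 0.40), and the matrix proteoglycan genes DCN and LUM changed by -4.61 ± 0.34 and -4.88 ± 0.64. The edgeR adjusted p-values of these genes ran from 0.00011 to 0.00219.

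Against control, 929 genes differed in PAX6-GOF by the edgeR test, 474 higher and 455 lower, with 715 over 2-fold. GDF10, a TGF-beta family ligand, had 316 counts against 0 in control and was at least 135-fold higher. The receptor phosphatase gene PTPRO had 371 against 1 count, a ratio of 477 (counting interval 85.1 to 18900). The zinc finger gene PLAGL1 rose by 7.67 ± 0.32 to 38.0 CPM from 0.186 CPM, with the smallest edgeR adjusted p of the comparison (3.2e-06). FGF14 (7.53 ± 0.53) and KCNC2 (6.60 ± 0.86), both of which act on neuronal excitability, rose with WSCD2 (6.68 ± 0.69), the inhibin subunit gene INHBB (6.33 ± 0.56), the focal adhesion gene TNS1 (5.49 ± 0.84) and the ETS factor gene ERG (5.49 ± 0.45). Downward, VWDE had 2 against 381 counts (ratio 0.00675, counting interval 0.000814 to 0.0245). A2M changed by -6.91 ± 1.42, NKAIN4 by -6.85 ± 1.06 and LPL by -5.93 ± 0.44. The lysophosphatidic acid receptor gene LPAR3 (-5.54 ± 0.47), the desmocollin gene DSC3 (-5.17 ± 0.81), the olfactory receptor gene OR51B4 (-5.13 ± 0.68) and the synaptic scaffold gene DLGAP2 (-5.02 ± 1.02) followed. All 3 PAX6-GOF libraries lay beyond all 3 controls in each, as the rule for named genes required, with edgeR adjusted p at most 0.023.

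The neuronal differentiation list shifted higher in PAX6-GOF, with 5 of 29 genes rising and 2 falling (9 and 2 adjusted over the list alone). Its camera adjusted p was 0.000467 (adjusted p = 0.296 with an estimated correlation). MAP2, the synaptic vesicle fusion gene SNAP25 (1.88 ± 0.26) and the secretory granule gene CHGB (2.01 ± 0.31) rose, while NEFL fell by 3.40 on the log2 scale. Targets of p53 and cell cycle inhibitors shifted lower, with 6 of 27 falling and 11 lower adjusted over the list alone (camera adjusted p = 0.00016; adjusted p = 0.779 with an estimated correlation). Among them were the cyclin-dependent kinase inhibitor genes CDKN1C (-3.92 ± 0.73) and CDKN1A (-1.87 ± 0.39), TP53INP1 (-2.33 ± 0.54) and the secreted stress factor gene GDF15 (-2.24 ± 0.52). CDKN2A again rose, by 2.24 ± 0.45 (edgeR adjusted p = 0.0207, higher in 3 of 3 libraries). The list of MYC targets and ribosome biogenesis shifted higher with 0 of 37 genes called in either count (median 0.20; camera adjusted p = 0.0051, adjusted p = 0.964 with an estimated correlation). MYC itself lay at 1978 ± 516 CPM in control and 3229 ± 529 CPM in PAX6-GOF, a difference that did not pass (0.71 ± 0.25 by edgeR). The glycolysis and hypoxia list, with 0 of 29 called in either count, had a median of 0.27 and a camera adjusted p of 0.015 (adjusted p = 0.779 with an estimated correlation). Of its 29 genes 8 lie on chromosomes 8, 10, 16 and 18, and with the positional adjustment the list no longer passed (adjusted p = 0.0638); 4203 genes had an edgeR p under 0.05 in this comparison.

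In the list of PAX6-associated eye and forebrain genes MAF and SIX6 rose (2 of 15; 5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.404), SIX6 with 46 against 2 counts (ratio 29.6, counting interval 7.73 to 251). Of 36 photoreceptor genes RBP3 (1.54 ± 0.31) and AIPL1 (2.01 ± 0.46) rose over all genes and adjusted over the list alone, with a camera adjusted p of 0.0621. Both were lost with the positional adjustment (edgeR adjusted p = 0.0786 and 0.0795). The count of PAX6-GOF calls was 418, 314 and 411 without PAX6-GOF 1, 2 and 3, 1493 with no filter on low counts and 1813 with DESeq2. The MYC target list no longer passed camera without control 3 (adjusted p = 0.538), nor did the glycolysis list without control 4 (0.231). With limma-voom the calls of DSC3 and DLGAP2 were lost (adjusted p = 0.0816 and 0.113). Leaving out PAX6-GOF 2 ended the calls of SIX6 (0.0669) and VWDE (0.053). Leaving out 1 of several libraries ended those of A2M, DLGAP2, CDKN1C, CDKN1A, TP53INP1, GDF15, RBP3 and AIPL1 (edgeR adjusted p up to 0.124, 0.112, 0.0898, 0.112, 0.159, 0.152, 0.0847 and 0.148).

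PAX3-GOF and PAX6-GOF differed directly in named neuronal, photoreceptor, muscle and laminin genes. The control libraries do not enter these differences, though they enter the spread they are tested against. GAP43 (-2.97 ± 0.35), MAP2 (-1.93 ± 0.24), SNAP25 (-1.79 ± 0.26) and MAP1B (-1.38 ± 0.16) were lower with PAX3. So were 4 members of the photoreceptor list, RBP3 (-2.37 ± 0.32), THRB (-2.61 ± 0.37), ARR3 (-2.73 ± 0.41) and RBP4 (-2.50 ± 0.44), of which RBP4 is not specific to photoreceptors. EYA1 (2.82 ± 0.40), the acetylcholine receptor gene CHRND (2.19 ± 0.28) and the laminin gene LAMA4 (3.84 ± 0.43) were higher, while LAMA1 stood at -5.28 ± 0.29. In each the 3 libraries of one group lay beyond the other 3, with edgeR adjusted p from 7.26e-06 to 0.00573.

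Between both gain-of-function groups 2575 genes differed by edgeR, 1280 higher and 1295 lower in PAX3-GOF. With the positional adjustment 2235 genes differed, 1239 higher and 996 lower in PAX3-GOF, and 1953 of them were among the original calls. The near balance of higher and lower calls was thus not kept once shifts along chromosomes, described below, were removed. The genes taken by fitted change above PAX6-GOF, which does not rank genes at 0 to 3 counts, were PAX3 (12128 against 1 count, ratio 11600, counting interval 2090 to 459000), C2CD4C (at least 595-fold), ALX4 (10.83 ± 0.95), PID1 (1692 against 1 count, ratio 1620, counting interval 291 to 64100) and THEG (at least 112-fold). Furthest below among protein-coding genes with a mean of at least 1 CPM were the neuropeptide gene CCK (-7.20 ± 0.67, 0.183 against 26.8 CPM), WSCD2 (-7.18 ± 0.73), FGF14 (-7.15 ± 0.52), the mechanosensitive channel gene PIEZO2 (-6.58 ± 0.46) and ZNF536 (-6.42 ± 1.22). PAX6 itself was lower by 3.84 ± 0.60 (log2 change -3.84, edgeR adjusted p = 0.0029), and OTX2 did not differ past the threshold (-0.19 ± 0.14, adjusted p = 0.401).

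Of the fixed lists 9 of 32 passed by camera, 7 lower and 2 higher in PAX3-GOF. Neuronal differentiation had 12 of 29 genes lower and 2 higher (19 and 2 adjusted over the list alone; camera adjusted p = 4.59e-07, adjusted p = 0.0775 with an estimated correlation). The photoreceptor list had 10 of 36 lower and 1 higher (13 and 3 adjusted over the list alone; camera adjusted p = 0.000963, adjusted p = 0.459 with an estimated correlation). In the glycolysis and hypoxia list 9 of 29 were lower and 19 adjusted over the list alone (camera adjusted p = 4.59e-07, adjusted p = 0.459 with an estimated correlation), with SLC2A1 at -1.05 ± 0.17, PGAM1 at -1.15 ± 0.21 and PDK1 at -0.95 ± 0.19. For ATF4 and amino acid genes 7 of 25 were lower and 10 adjusted over the list alone (camera adjusted p = 3.03e-05, adjusted p = 0.471 with an estimated correlation), DDIT4 by -2.29 ± 0.39 and the asparagine synthetase gene ASNS by -1.05 ± 0.20. Cholesterol synthesis had 5 of 25 lower and 6 adjusted over the list alone (camera adjusted p = 0.000963, adjusted p = 0.475 with an estimated correlation), with EBP, a sterol isomerase gene, at -0.51 (edgeR adjusted p = 0.029, lost without 1 library in 6 of 9 cases). Nuclear genes of oxidative phosphorylation had 4 of 33 lower in both counts (camera adjusted p = 0.00155, adjusted p = 0.623 with an estimated correlation), 9 of the 33 lying on chromosomes 8, 10, 16 and 18. Its leading gene COX4I1 moved from -0.80 ± 0.14 to -0.10 with the positional adjustment and NDUFB8 from -0.52 to 0.00 (edgeR adjusted p = 0.685 and 0.996), while the list still passed (0.00851). MYC targets shifted lower with 0 of 37 called in either count (camera adjusted p = 0.00155, adjusted p = 0.686 with an estimated correlation). With the positional adjustment 5 glycolysis and hypoxia, 3 cholesterol synthesis, 8 photoreceptor, 13 neuronal and 7 ATF4 and amino acid genes were lower. These lists all still passed (camera adjusted p at most 0.00106).

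The myogenic list stood higher in PAX3-GOF, with 12 of 24 genes higher and 15 adjusted over the list alone (camera adjusted p = 0.00104; adjusted p = 0.541 with an estimated correlation). EYA4 was at least 21.7-fold higher, and CHRNA1 by 1.25 ± 0.26. Against control the list did not pass in PAX6-GOF, where 4 of 24 genes fell and 1 rose (5 and 1 adjusted over the list alone; median -0.70, camera adjusted p = 0.0621). CHRNA1 fell there by 1.59 and CHRND by 1.32 on the log2 scale (edgeR adjusted p = 0.0072 and 0.0255, lower in 3 of 3 libraries), so part of the direct difference is a fall in PAX6-GOF. The CHRND call there was lost without 1 library in 5 of 9 cases (up to 0.117). The library PAX3-GOF 1, with its high muscle structural genes, is 1 of the 3 on the higher side. The extracellular matrix list had 8 of 40 genes higher and 2 lower (15 and 2 adjusted over the list alone; camera adjusted p = 0.0025, adjusted p = 0.475 with an estimated correlation), COL4A1 by 0.73 ± 0.11 and LAMC1 by 0.96 ± 0.15. Against control this list had 5 genes lower and 2 higher in PAX6-GOF (10 and 3 adjusted over the list alone; median -0.45, camera adjusted p = 0.0797) and 3 higher and 2 lower in PAX3-GOF (8 and 5; 0.159). The count of calls was 4450 without control 3, 1690 and 1512 without PAX3-GOF 4 and 5, 1569, 1085 and 1196 without PAX6-GOF 1, 2 and 3, and 4766 when only these 6 libraries were fitted. The calls of NDUFB8 (up to 0.0913 without 1 library) and CHRNA1 (up to 0.0583) were lost without single libraries, and that of ZNF536 with limma-voom (0.0518).

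LPL, NEFL and CCND1 were lower than in control in both gain-of-function groups, and LGR5 and LAMA1 went opposite ways. In all, 121 genes were higher in both comparisons with control and 119 lower in both, where independent lists of these sizes would share 13.7 and 11.9. That expectation leaves out the shared controls. Of the genes named above for PAX3-GOF, SYNDIG1, FSTL4, CCDC33, EYA1 and GAD1 were also called higher in PAX6-GOF, and NOVA1, CILP2 and NEFM lower. Of those named for PAX6-GOF, PLAGL1, PTPRO, INHBB and MAF were also called higher in PAX3-GOF, and LPAR3, NKAIN4, TWIST1 and LUM lower. Named for both groups, CDKN2A was called higher and GDF15 lower in each. In the fit of all libraries these calls were not particular to 1 virus, though the shared controls may contribute. The MAF call in PAX3-GOF (edgeR adjusted p = 0.0475) was lost without 1 library in 7 of 9 cases. That of EYA1 in PAX6-GOF (edgeR adjusted p = 0.0309) was lost in 4 of 9. PTPRO had 14 against 1 count in PAX3-GOF (ratio 17.2, counting interval 2.62 to 729). Another 18 genes were higher with PAX3 and lower with PAX6, and 18 the reverse, against 13.1 and 12.4 for independent lists. LGR5, a receptor that strengthens WNT signals, rose by 2.89 in PAX3-GOF and fell by 3.09 in PAX6-GOF, from 5.73 CPM to 42.2 and 0.663 CPM (direct difference 5.97 ± 0.45, edgeR adjusted p = 4.03e-05). LAMA1 fell by 1.12 and rose by 4.15, PIEZO2 fell by 3.76 and rose by 2.82, and BAMBI, a decoy receptor of TGF-beta family signals, fell by 1.56 and rose by 1.54 on the log2 scale. The CCND1 call in PAX6-GOF (-2.85, edgeR adjusted p = 0.0087) was lost without PAX6-GOF 2 or 3 (0.053 and 0.0549). The LAMA1 call in PAX3-GOF (edgeR adjusted p = 0.0322) was lost without 1 library in 7 of 9 cases. Across 21873 genes, which are not independent replicates, the changes of both comparisons had a Pearson correlation of 0.232 and a Spearman correlation of 0.187. The covariance was 0.143. In 50 simulations of unchanged groups that share drawn controls it averaged 0.0861 with 1 spread for all groups (mean simulated correlation 0.489). It averaged 0.101 when each group kept its own spread, wider in the controls (mean simulated correlation 0.578). The 3 controls cannot be split into parts of 2 libraries, so part of the excess may come from the shared controls. The count of genes changed alike, 240 in the fit of all libraries, was 146 without PAX3-GOF 5, 118, 95 and 113 without PAX6-GOF 1, 2 and 3, 385 with no filter on low counts, 452 with DESeq2 and 139 when each pair of groups was fitted alone.

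**Figure D3:**
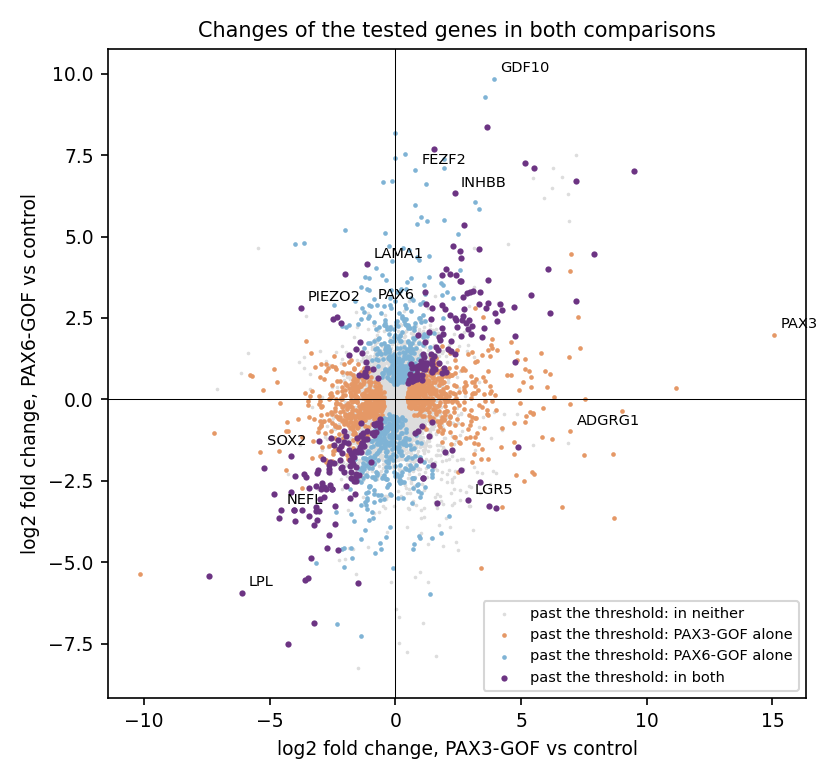
Log2 fold changes of the 21873 tested genes against control, for PAX3-GOF (horizontal axis) and PAX6-GOF (vertical axis), coloured by which comparison passed the edgeR threshold. The 240 genes that changed alike in both lie at the lower left and upper right, LPL among them, and LGR5, LAMA1 and PIEZO2 lie in the other corners; fitted values at the far right such as PAX3 depend on 0 counts in control.

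Whole chromosomes shifted with the groups. Over protein-coding genes above 5 CPM on average, the median log2 change was 0.60 on chromosome 18 (160 genes, 93.8% higher) and -0.32 on chromosome 8 (384 genes) in PAX3-GOF. In PAX6-GOF it was 0.47 on chromosome 16 (489 genes, 93.7% higher), 0.26 on chromosome 10 (414 genes, 82.4% higher), 0.38 on chromosome 18 and -0.21 on chromosome 8. In PAX3-GOF the chromosome 16 median was 0.185 before 20 Mb and -0.149 beyond. The medians of the other 19 chromosomes ran from -0.11 to 0.22 in both comparisons, highest on chromosome 21 (0.219 and 0.218, with 77.1% and 81% of 105 genes higher), which in PAX6-GOF is as far as chromosome 8. These 4 chromosomes were singled out after their values were seen, and held 244 of the 1202 PAX3-GOF calls and 199 of the 929 PAX6-GOF calls. Without their genes 909 and 665 calls were made, and with the positional adjustment 1022 and 714, of which 917 and 662 were among the original calls. Between PAX3-GOF and PAX6-GOF the median was -0.526 on chromosome 16, with 152 of 158 called genes lower. On chromosome 10 it was -0.414, with 113 of 122 lower, and the 4 chromosomes held 532 of the 2575 calls. Control libraries 1, 3 and 4 also differed from each other, with medians around the control mean of 0.297, -0.302 and 0.024 on chromosome 16, 0.18, -0.158 and 0.01 on chromosome 10, -0.234, 0.154 and 0.116 on chromosome 18 and -0.157, 0.01 and 0.134 on chromosome 8. The PAX6-GOF libraries overlapped this spread on chromosome 8 (-0.256, -0.154 and -0.161) and came near it on chromosome 10 (0.199, 0.304 and 0.342).

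**Figure D4:**
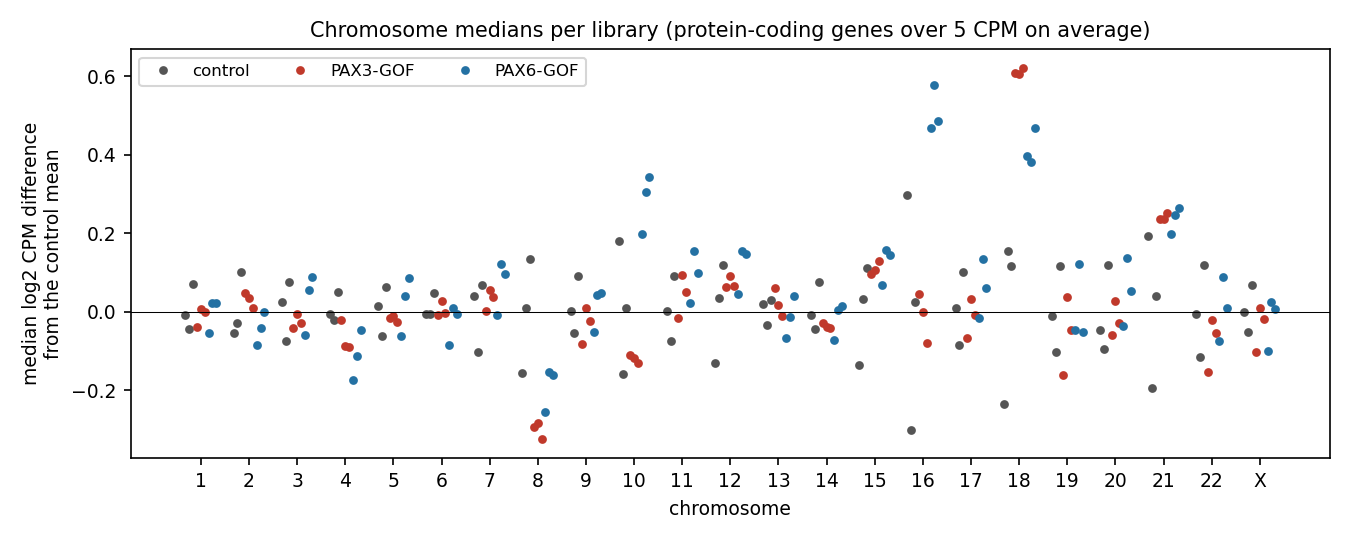
Median log2 CPM difference from the control mean per chromosome (horizontal axis) and library (points), over protein-coding genes above 5 CPM on average. The 3 PAX3-GOF libraries lie at 0.605 to 0.621 on chromosome 18 and the 3 PAX6-GOF libraries at 0.467 to 0.577 on chromosome 16.

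The authors' deposited tables hold 26889 genes, of which 1563 pass an adjusted p of 0.05 for PAX3-GOF (819 higher, 744 lower) and 1539 for PAX6-GOF (787 higher, 752 lower). Of the edgeR calls made here 1052 and 814 were among them, all with the direction of the deposited tables. For PAX6 in PAX6-GOF the authors' deposited table gives a log2 fold change of 2.693 with adjusted p = 8.93e-07.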

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

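The shares of reads per transcript were examined only after the gene-level results were seen, and no explanation was tested for them. They come from the transcript level, which the comparisons above sum over. Of the PAX6 reads in the PAX6-GOF libraries 43.7% were assigned by the authors' Salmon run to the transcript PAX6-268, which took 0 reads in the control libraries. Another 40.4% went to PAX6-238, which took 0.8% of the PAX6 reads in control. In PAX3-GOF 19.9% of the PAX3 reads were assigned to PAX3-210, a transcript annotated as a retained intron, while 74.7% went to the protein-coding transcript PAX3-207 and the control libraries held no PAX3 reads. No group has 4 libraries, so single libraries were not tested for standing apart from their group.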

How the results depend on the processing

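The positional adjustment and the test without 4 chromosomes were chosen after the data were seen; the other alternatives were planned. Genes past the threshold moved over 1.5 times for PAX3-GOF against control (1202) with DESeq2 (1954) and in a fit of the compared groups alone (612). For PAX6-GOF against control (929) this held with no filter (1493) and DESeq2 (1813), for PAX3-GOF against PAX6-GOF (2575) in the fit of the groups alone (4766), and for genes changed alike (240) with no filter (385), DESeq2 (452) and the groups alone (139). Leaving out 1 library gave 672 to 2193, 314 to 1376, 1085 to 4450 and 95 to 316. The cause was not tested, and with no filter 42263 genes were tested. The fit of all libraries uses 1 spread per gene. Estimated per group, the median coefficient of variation between libraries was 0.326 in control, 0.245 in PAX3-GOF and 0.187 in PAX6-GOF. Adjusted p-values against control thus rest on a spread pooled with narrower groups. Lists past camera (6, 4 and 9) went to 0, 0 and 0 with an estimated correlation and to 7 with DESeq2 size factors for PAX6-GOF; fry, which tests a list against no change and not against other genes, passed 2, 2 and 14, of which 1, 1 and 7 were among the camera lists; without 1 library they were 4 to 12, 4 to 8 and 9 to 13. OTX2 in PAX6-GOF passed with DESeq2 (0.503). PAX6 ranged from 2.59 to 3.74 without 1 library in PAX6-GOF. PLK1 and CDT1 on chromosome 16, lower in PAX3-GOF than PAX6-GOF (-0.49 and -0.61), turned to 0.093 and 0.107 with the positional adjustment and no longer passed (adjusted p = 0.666 and 0.638); the adjustment removes the shift of their chromosome. Same-numbered libraries showed no clear common deviation, with correlations of -0.047 and 0.155 for control with PAX3-GOF. They were -0.018 and -0.27 for control with PAX6-GOF and 0.077 for the numbered pair of both. So few values cannot tell whether equal numbers share a culture or a day, which the sources used here do not say. A replicate block, which leaves few residual degrees of freedom, called 91, 55 and 50 genes and 8 changed alike, with PAX6 at 3.29 in PAX6-GOF (adjusted p = 0.117) and at -4.31 between the viruses (0.101). Of 273 named gene and leading list member calls, 166 passed without each of the 9 libraries; 271 of 272 passed with DESeq2, 252 with limma-voom, 220 with the length offset, 237 with the positional adjustment, 238 of 271 in the fit of the groups alone and 49 with the block. Of the 10 splits of the 6 libraries of a comparison only the real 1 gave as many calls, with 1202, 929 and 2575 against at most 1, 0 and 0 in the others; 10 splits are too few for a share under 0.05. Depth limits genes at a few counts, and the simulated data show that changes of 2-fold or less are mostly missed.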

Other observations

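Ligands, receptors and targets of developmental signals differed from control in both gain-of-function groups, and the members of a list went in both directions. Of 30 WNT genes 4 rose and 1 fell in PAX3-GOF, among them the WNT target SP5 (3.03 ± 0.26), LGR5 and the receptor gene FZD2 (1.43 ± 0.25). In PAX6-GOF 2 rose and 2 fell, with the WNT inhibitor gene APCDD1 higher (2.51 ± 0.31) and LGR5 lower. Of 17 Hedgehog genes 3 rose and 2 fell in PAX3-GOF, with CCND2 and GAS1 (1.64 ± 0.24) higher. HHIP, an antagonist and target of the pathway, was lower there (-2.22 ± 0.24). In PAX6-GOF 1 rose and 3 fell (2 and 7 adjusted over the list alone, median -0.55). Among 28 BMP and TGF-beta genes 4 rose and 4 fell with PAX3, SMAD9 by 2.05 ± 0.28 and BMP2 by -2.69 ± 0.35, and 4 rose and 3 fell with PAX6, where TGFBR2 changed by -2.34 ± 0.31. Of 60 axon guidance genes 7 rose and 4 fell with PAX3, with EPHB3 (4.96 ± 0.49) and ROBO2 (3.63 ± 0.47) higher and EPHA3 (-2.40 ± 0.28) and UNC5D (-2.58 ± 0.32) lower. With PAX6 7 rose and 5 fell, with EPHB2, SEMA7A (2.58 ± 0.29) and CRMP1 (1.56 ± 0.21) higher and EPHA3 (-3.29 ± 0.29) lower. All these genes had edgeR adjusted p at most 0.00839, with the 3 libraries of the virus on one side of the control mean, and none of these 4 lists passed camera in either comparison (the smallest adjusted p was 0.0584, Hedgehog in PAX6-GOF). In PAX3-GOF the axon guidance and WNT lists had medians of -0.04 and -0.06 but means of 0.19 and 0.16.

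Markers of other lineages changed gene by gene. In the neural crest list 2 of 20 genes rose and 2 fell with PAX3 (4 and 4 adjusted over the list alone). ZIC5 (3.52 ± 0.50) and ZIC2 (2.33 ± 0.37), zinc finger genes of the dorsal neural tube, rose and TWIST1 fell (camera adjusted p = 0.760 for the list). The TWIST1 call was lost without PAX3-GOF 1, 4 or 5 (edgeR adjusted p up to 0.0786). Of 10 endothelial and mesenchymal markers 1 rose and 1 fell with PAX3 (1 and 5 adjusted over the list alone; median -0.77, camera adjusted p = 0.0896). With PAX6 2 fell, DCN and LUM, in both counts (median -0.77, mean -1.16, camera adjusted p = 0.0504, and 0.0298 with the positional adjustment). TEK, an endothelial receptor gene, rose by 4.73 ± 0.49, LUM fell by 3.35 and the astrocyte gene CLU fell by 1.92 on the log2 scale with PAX3. The matrix gene CCN2, a target of YAP, fell by 4.60 with PAX6, and the GABA receptor gene GABRB2 had 2 against 207 counts there (ratio 0.0124, counting interval 0.00149 to 0.0454). EN1, a homeobox gene of the midbrain and cerebellum, had 57 against 0 counts in PAX6-GOF, at least 24.4-fold higher, and its edgeR adjusted p went from 0.0102 to 0.0604 without PAX6-GOF 2. The cell cycle list had 0 of 40 genes called in both comparisons with control (camera adjusted p = 0.347 and 0.894).

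Of the tests below, the share of genes with the sign of their chromosome's median, both tests of the muscle genes and the simulations with the own spread of each group were chosen only after the result was seen, the first in place of a test on genes without a call and the last in place of simulations with 1 spread for all groups (highest 0.0914); the others were written down before it. The 4 chromosome-wide shifts were weighed against transcript bias, regulation of some genes and copy number. After a trend on GC content and transcript length was removed, the PAX6-GOF medians were still 0.484 on chromosome 16 and 0.299 on chromosome 10. In PAX3-GOF they were 0.582 on chromosome 18 and -0.341 on chromosome 8, which argues against that trend as the cause. Of all genes on chromosome 16, 93.7% shared the sign of its median in PAX6-GOF, and 82.4% did so on chromosome 10. In PAX3-GOF 93.8% did so on chromosome 18 and 85.7% on chromosome 8, so the shifts were not limited to a few genes. The chromosomes were singled out after their values were seen, and a median far from 0 goes with a high share. These shares therefore cannot decide whether regulation of a subset of genes contributed. Genes below and above the median expression were at most 0.147 apart in these comparisons (chromosome 18 in PAX3-GOF), just under the bound of 0.15 set beforehand. They shifted alike on each chromosome, as a difference in chromosome copy number between cultures would give. Such a difference is a candidate explanation that stays open, since no DNA was analysed here and chromosome-wide regulation would look alike; the part of chromosome 18 beyond 50 Mb had a median of 0.94 against 0.54 before it in PAX3-GOF.

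Myogenic genes were high in PAX3-GOF 1, where 13 of 15 embryonic muscle genes reached 10 CPM against 8, 10 and 9 in controls 1, 3 and 4 and 5 in each of PAX3-GOF 4 and 5. A mislabelled library is argued against by PAX3 itself, at 86.3 CPM there and 74.9 and 79.7 CPM in the other two. Cells of mature skeletal muscle would bring ACTA1, the most abundant muscle actin, which lay at 1.75 CPM, within the 1.16 to 2.10 CPM of the controls; MB, MYH2 and CASQ1 lay at 0.821, 0.111 and 0.177 CPM. The bound on ACTA1 was added after the count of mature genes was seen. Of 12 mature genes 6 reached 10 CPM in PAX3-GOF 1, against 1 to 2 in the controls. These were TNNC2 at 139, MYLPF at 137.339, CKM at 124, TNNT3 at 83.782, MYH7 at 74.978 and TNNI2 at 18.362 CPM. MB also lay above the controls, which held at most 0.045 CPM. That count alone went with mature muscle. The mature genes thus pointed both ways, and mature muscle stays open. A larger share of immature muscle-like cells in that culture may account for the pattern and were not separated here from a stronger response to PAX3, and MYOD1, a muscle regulator looked up after these values, lay at 189, 157 and 146 CPM in PAX3-GOF 1, 4 and 5, 109 to 205 CPM in the controls and 72.9 to 91.2 CPM in PAX6-GOF.

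The genes changed alike in both comparisons were weighed against the controls that the comparisons share. The observed covariance of 0.143 lay above the highest of 50 simulations of unchanged groups that kept the own spread of each group (0.1055), but by less than 2 times, and simulated settings exclude nothing, so shared controls stay open. Leaving out 1 control library lowered the count of 240 to 169 at the least (without control 4) and gave 311 and 257 without controls 1 and 3. The count thus stayed above the bound set beforehand for a single unusual control. It also follows the spread and the number of libraries, and it fell further without each PAX6-GOF library, as given above. An unusual control is therefore not excluded. A common response to a transduced PAX gene may explain the pattern, as may a difference of the RFP cultures from both others; with RFP as the only control, these data do not separate them.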
